A study of Arabidopsis thaliana with 12 samples.

How the data were processed

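RNA from 9-day-old Arabidopsis thaliana seedlings was measured on 12 arrays, 2 for each of 6 groups. Per the labels, 4 groups were seedlings carrying LEAFY-GR, sampled at 8 h after mock treatment, dexamethasone, cycloheximide, or dexamethasone with cycloheximide. The other 2 groups were Landsberg erecta seedlings and 35S::LFY seedlings, which the labels call untreated. The labels also give a lot batch, and each group had 1 array in lot 1 and 1 in lot 2. They do not say whether the 2 arrays of a group came from separately grown seedlings, so the p-values measure only the spread between these samples, which may be technical.

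The authors deposited 1 linear intensity for each of 22810 probe sets on each array, with 1 decimal, no detection calls and no background values. The software that made these intensities is not given in the sources used here. The deposited intensities had already been scaled, judging from the values, because the mean after trimming 2% from each end was 150.01 to 150.02 on all 12 arrays. That statistic had been required to lie within 5% of its mean over the arrays for the table to be used as deposited, and no further normalisation was applied. The number of arrays limits the precision of every value.

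Probe sets were named through the array's annotation table and a table of RefSeq genes of the assembly TAIR10.1, which was used for names only. The annotation table listed 14016 probe sets, of which 13513 had 1 gene and 503 had several. Of those with 1 gene, 13436 matched a locus and 77 did not, giving 13286 loci, and 1535 loci had a symbol other than the locus code. In all, 8807 tested probe sets are unnamed here, those not listed and the 77 without a matching locus, which does not mean that they have no gene. No gene was named from a probe set with several genes. The probe set of LFY itself is among those not named here, so the level of LFY could not be used to check the labels.

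The 64 Affymetrix control probe sets were left out of all tests, which left 22746. Intensities were converted to log2(intensity + 10), where 10 is the 20th percentile of all values rounded to 1 digit, and fold changes on this scale understate the change of dim probe sets. limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 12 arrays, with 6 residual degrees of freedom and empirical Bayes moderation with an intensity trend that added 5.3 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the tested probe sets, and a probe set was called changed at an adjusted p under 0.05. Errors of log2 changes are standard errors from this fit, which shares 1 spread per probe set among all groups. Errors of signals are standard deviations of 2 arrays. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for annotation and plots.

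The contrasts were dexamethasone against mock, dexamethasone with cycloheximide against cycloheximide, 35S::LFY against Landsberg erecta, cycloheximide against mock, the difference between the dexamethasone responses with and without cycloheximide, the mean of the 3 LEAFY contrasts, and mock-treated LEAFY-GR against Landsberg erecta. Overlaps of calls among the 3 LEAFY contrasts, which share no arrays, were tested with one-sided Fisher exact tests adjusted over 6 overlaps. No group of seedlings without LEAFY-GR received dexamethasone in the samples analysed here.

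The gene lists, the contrasts, the test, the alternatives and the rule for naming genes were fixed before the data were examined, except where stated. The rule named LFY on every array, which could not be met, and up to 10 genes with the highest and 10 with the lowest log2 change among called probe sets that had the same direction in both lots and a single locus with a symbol, for each of the 3 LEAFY contrasts, cycloheximide against mock and the mean of the 3. Where fewer than 5 genes passed, the 5 smallest p-values would have been named as not passing, which did not occur. It also named every measured floral organ identity gene and reported LEAFY target, up to 4 members of each other list with the smallest p-values, up to 20 genes that passed in the same direction in all 3 LEAFY contrasts, with or without a symbol, and the 10 smallest p-values that passed for the difference in dexamethasone response. All measured members of the lists tested as groups are given, which goes beyond the 4 of the rule. Genes given by locus code, probe sets given by their identifier and genes named for mock against Landsberg erecta lie outside the rule unless they fall under its last 2 parts, and they were chosen after their values were seen.

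The 16 gene lists held 262 entries, of which 36 were measured by a named probe set, covering 35 distinct loci. The 3 lists with at least 5 measured members, for auxin response, flowering time and immunity, were tested with limma's camera at a preset correlation of 0.01, adjusted over the 3 lists and 6 contrasts. Camera with an estimated correlation and fry were run as alternatives. Families of at least 8 loci that share the opening letters of their symbol, and loci encoded in an organelle, were tested in the same way and were chosen after the values were seen, as was the difference between the 35S::LFY and dexamethasone responses.

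Arrays of the same lot deviated together from their group means in most pairs of groups, with a correlation over 0.1 in 12 of 15 pairs, a median of 0.144 and a range of 0.049 to 0.334. As the labels name the lot, a fit with the lot as a block was run beside the main one. In that fit limma called 0 probe sets different between the lots.

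The alternatives were quantile normalisation, scaling to equal medians, scaling to the hybridisation controls (chosen after seeing the data), pseudocounts of 5 and 40, leaving out the dimmest 40% of probe sets, moderation without the trend, fitting only the groups compared, the lot as a block, leaving out each array in turn, an adjusted p of 0.1, and a rule of 2-fold in both lots without a test. Where an array was left out, the lone array of its group was assumed to vary like the other groups. The median log2 change of all probe sets lay within 0.1 of 0 in each single contrast, and scaling to the hybridisation controls moved it to 0.168 for dexamethasone, -0.127 for cycloheximide and -0.221 for the difference in dexamethasone response. For the difference between the 35S::LFY and dexamethasone responses the median was -0.108, and -0.211 with that scaling.

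The fit was tested on simulated data made from the 22746 probe sets, with 100 probe sets changed by each size. At a log2 change of 2 it recovered 89% of them for dexamethasone against mock, 78% for dexamethasone with cycloheximide, 78% for 35S::LFY, 70% for cycloheximide, 52% for the difference in dexamethasone response and 100% for the mean of the 3. At a log2 change of 1 the shares were 31%, 35%, 34%, 30%, 9% and 75% in the same order. The simulations without any change gave 0 calls in each of these contrasts, and those with changes called 2 to 7 unchanged probe sets. Their noise was independent between arrays, with the same spread in all groups for a given probe set. They leave out the shared lot deviations of the real arrays, so they do not bound the false calls there. Changes were added on the log2 scale with no floor, and real spreads differed between groups. The shares recovered may thus be too high for falls of dim probe sets and for the contrasts with cycloheximide.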

Results

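The arrays compared seedlings in which the floral regulator LEAFY was activated or overexpressed with matched controls. LEAFY-GR is a fusion of LEAFY to the hormone-binding part of the glucocorticoid receptor, which dexamethasone activates, and cycloheximide inhibits protein synthesis. Under the 35S promoter LFY is expressed constitutively. The series is titled as a search for LEAFY targets, and the design allows the response to activation to be compared with and without protein synthesis. Each of the 6 groups had 2 arrays, with median signals of 49.8 to 69.4 and 15.0% to 17.7% of values below the pseudocount per array. Replicate arrays correlated at 0.959 to 0.979 on the log2 scale. The leading principal component held 76.2% of the variance and parted the 4 arrays with cycloheximide from the other 8. The ratio of 3′ to 5′ signal of GAPDH ranged from 0.97 to 1.30 over the arrays, and that of actin from 1.35 to 2.25. In both lots it was higher with dexamethasone than in mock, for GAPDH (1.17 against 1.12 and 1.28 against 0.97), actin (1.94 against 1.75 and 1.67 against 1.63) and ubiquitin (1.69 against 1.51 and 1.49 against 1.43). RNA quality is therefore not separated from the response to dexamethasone alone, the auxin response list included. With cycloheximide present, dexamethasone also went with a higher actin ratio in both lots (2.11 against 1.78 and 1.4 against 1.35). The ubiquitin ratio was higher too (1.74 against 1.72 and 1.5 against 1.4). That of GAPDH was higher in lot 1 (1.12 against 1.03) and lower in lot 2 (1.01 against 1.04). RNA quality is thus not separated from the dexamethasone response with cycloheximide, or from the mean of the 3 LEAFY contrasts.

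Dexamethasone raised 6 genes with a symbol and lowered 5. AR781 rose by 1.63 ± 0.21 log2 (462.2 ± 97.0 against 143.4 ± 39.5 in mock, n = 2, adjusted p = 0.00459), and GH3.17, an enzyme that conjugates auxin to amino acids, rose by 1.62 ± 0.29 (adjusted p = 0.0366). The β-glucosidase gene BGLU15 rose by 1.31, TBL38 by 1.27, the U-box ubiquitin ligase gene PUB23 by 1.26 and the zinc-finger gene STZ by 0.96. XTH19, a cell-wall xyloglucan enzyme, fell by 1.90 ± 0.24 to 5.9 ± 5.4, a level below the pseudocount, from 47.5 ± 1.6 (adjusted p = 0.0044). Falls were also measured for the β-glucosidase gene BGLU44 (-1.67), the sugar transporter gene SWEET11 (-1.26), the peroxidase gene Prx37 (-1.12) and scpl35 (-0.96).

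Larger changes were measured at loci known here by code only, chosen after their values were seen. AT5G60630 had a signal of 2729 ± 375 with dexamethasone and 53.6 ± 6.4 in mock, a log2 change of 5.43 ± 0.23 (adjusted p = 1.26e-06). AT5G49770 rose by 2.84, AT2G26390 by 2.66, AT1G73600 and AT1G24140 by 2.59 each and AT5G59680 by 2.12. AT5G55450 fell by 4.64 ± 0.34, from 367.0 ± 107 to 5.1 ± 4.3 (adjusted p = 0.000123). Next came AT5G50335 (-2.72), AT4G15690 (-2.55), AT2G39980 (-2.46) and AT5G22580 (-2.39). Signals lay below the pseudocount of 10 for AT5G55450 and AT5G50335 with dexamethasone, and for AT5G49770 and AT1G24140 in mock. The size and rank of those changes depend on the pseudocount.

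In all, limma called 108 of 22746 probe sets, 49 higher and 59 lower, and 93 of them changed at least 2-fold. With arrays scaled to equal medians the split was 29 higher and 67 lower. Of the 59 that fell, 23 were called higher in mock than in Landsberg erecta and 10 lower. Of the 49 that rose, 12 were higher there and 6 lower, against 910 and 869 of all 22746. Both comparisons use the same mock arrays, so high values on these arrays could contribute to the falls, which was not tested. Fewer probe sets passed when a single array was left out, 39 without dexamethasone replicate 1, 54 without dexamethasone replicate 2, 53 without mock replicate 1 and 33 without mock replicate 2. Without mock replicate 2 none of the 11 genes with a symbol passed (adjusted p from 0.0525 for XTH19 to 0.3 for STZ), and without dexamethasone replicate 1 only XTH19 did (from 0.0598 for AR781 to 0.212 for STZ for the rest). Without mock replicate 1, GH3.17, BGLU15, TBL38, PUB23, BGLU44, Prx37 and scpl35 were lost (0.0521 for BGLU15 to 0.211 for GH3.17), and without dexamethasone replicate 2, GH3.17, BGLU15, STZ, SWEET11 and scpl35 (0.0544 for SWEET11 to 0.198 for GH3.17). Of the loci given by code, AT4G15690 was lost in all 4 fits (adjusted p = 0.0751 and 0.198 without dexamethasone replicate 1 and 2, 0.14 and 0.157 without mock replicate 1 and 2), and the other 10 passed in all 4.

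Of the 4 measured floral organ identity genes, none passed with limma in any LEAFY contrast. Their log2 changes with dexamethasone were 0.65 ± 0.36 for JAG, 0.44 ± 0.30 for SPT, 0.27 ± 0.44 for UFO and 0.13 ± 0.20 for SPL, and UFO and SPL had mean signals of 17.0 and 5.0. The lists of reported LEAFY targets and of cell cycle genes had 0 members under a named probe set and were not tested here. Across all 35 measured list loci, 1 passed with dexamethasone (STZ, of the early stress list). With limma 0 passed with dexamethasone and cycloheximide or with 35S::LFY. An unadjusted p under 0.05 was found for 5, 3 and 4 loci in these contrasts in turn. All 6 measured flowering time genes (AGL24, FD, GI, AGL42, SMZ and SNZ), all 5 immunity genes, the 3 gibberellin receptor genes, the meristem genes CLV3 and LAS, the cytokinin response genes ARR15 and RR16, the dehydration genes COR15A and COR47, the photosynthesis genes LHCB4.1 and RCA, the root gene EXPA7, the clock gene GI, the flavonoid gene DFR and the ribosomal protein gene AT3G09630 failed to pass in these 3 contrasts. DFR had a log2 change of 1.17 ± 0.33 with dexamethasone (adjusted p = 0.263), and STZ 0.89 ± 0.17 with 35S::LFY (adjusted p = 0.0777). Each was the single measured member of its list, for which adjustment over the list alone leaves the p-value unadjusted. The flowering time list had a median of 0.46 with dexamethasone and a camera adjusted p of 0.147, or adjusted p = 0.541 with an estimated correlation.

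The auxin response list had 5 measured members (IAA29, GH3.3, WES1, LBD16 and LBD29), and none passed singly over all probe sets in a LEAFY contrast. As a group they were lower than other genes with 35S::LFY, where their median log2 change was -0.87 and camera gave an adjusted p of 0.00111, or adjusted p = 0.053 with an estimated correlation. In that contrast LBD29 had -1.17 ± 0.35, IAA29 -1.03 ± 0.32, GH3.3 -0.87 ± 0.40, LBD16 -0.26 ± 0.31 and WES1 -0.22 ± 0.17, and 2 of the 5 passed when adjusted over the list alone. With dexamethasone the median was -0.43 and the camera adjusted p 0.0475. It was 0.181 with an estimated correlation and 0.0717 with the lot as a block, and fry gave 0.141. GH3.3 had -1.58 ± 0.40 and WES1 -0.73 ± 0.17 there, the 2 members that passed when adjusted over the list alone. That call was also lost with scaling to equal medians (0.157) and without dexamethasone replicate 1 (0.337), mock replicate 1 (0.0579), mock replicate 2 (0.152), cycloheximide replicate 1 (0.0509), cycloheximide replicate 2 (0.0502), 35S::LFY replicate 1 (0.0535), 35S::LFY replicate 2 (0.0538), Landsberg erecta replicate 1 (0.0838) or Landsberg erecta replicate 2 (0.0809).

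With cycloheximide present, dexamethasone raised GH3.17 by 3.41 ± 0.29 log2 (280.0 ± 79.5 against 18.4 ± 13.5, n = 2, adjusted p = 0.000408) and EXPA8, an expansin that loosens cell walls, by 2.67 ± 0.22 (92.9 ± 5.1 against 6.2 ± 1.3, adjusted p = 0.000408). The homeobox gene HAT2 rose by 2.06 ± 0.24 and PS1 by 1.22 ± 0.20. UGT76E1, a glycosyltransferase gene, fell by 1.52 ± 0.21, from 25.4 and 38.1 to 3.7 and 5.2, below the pseudocount. Falls were also measured for PMEPCRF (-1.06 ± 0.16) and the cellulose synthase-like gene CSLD2 (-1.02 ± 0.17). Among loci chosen after their values were seen, AT5G60630 rose by 4.51 ± 0.23 to 713.4 ± 57.5, AT1G33790 by 3.44, AT2G47560 by 2.59 and AT5G49770 by 2.36, and AT5G55450 fell by 2.11.

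The count was 44 probe sets in limma, 31 higher and 13 lower. The split was 27 higher and 4 lower with arrays scaled to equal medians, and 17 and 4 with scaling to the hybridisation controls. Leaving out dexamethasone with cycloheximide replicate 1 gave 25 calls and replicate 2 gave 20. GH3.17, EXPA8 and AT5G60630 passed whichever of the 4 arrays was left out, while HAT2 was lost without dexamethasone with cycloheximide replicate 2 (adjusted p = 0.0502), as were PS1 (0.168), UGT76E1 (0.0839), PMEPCRF (0.114) and CSLD2 (0.174). Without replicate 1 of that group PS1 (0.165), UGT76E1 (0.122) and PMEPCRF (0.167) were lost, without cycloheximide replicate 1 PS1 (0.103), PMEPCRF (0.104) and CSLD2 (0.129), and without cycloheximide replicate 2 UGT76E1 (0.0772) and CSLD2 (0.117). Among the loci, AT5G55450 was lost in all 4 fits (adjusted p = 0.18 and 0.137 without dexamethasone with cycloheximide replicate 1 and 2, 0.133 and 0.0621 without cycloheximide replicate 1 and 2). AT5G49770 was lost without either of the former arrays (0.076 and 0.0902), AT2G47560 without replicate 1 (0.076) and AT1G33790 without replicate 2 (0.0619) of dexamethasone with cycloheximide.

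**Figure D1:**
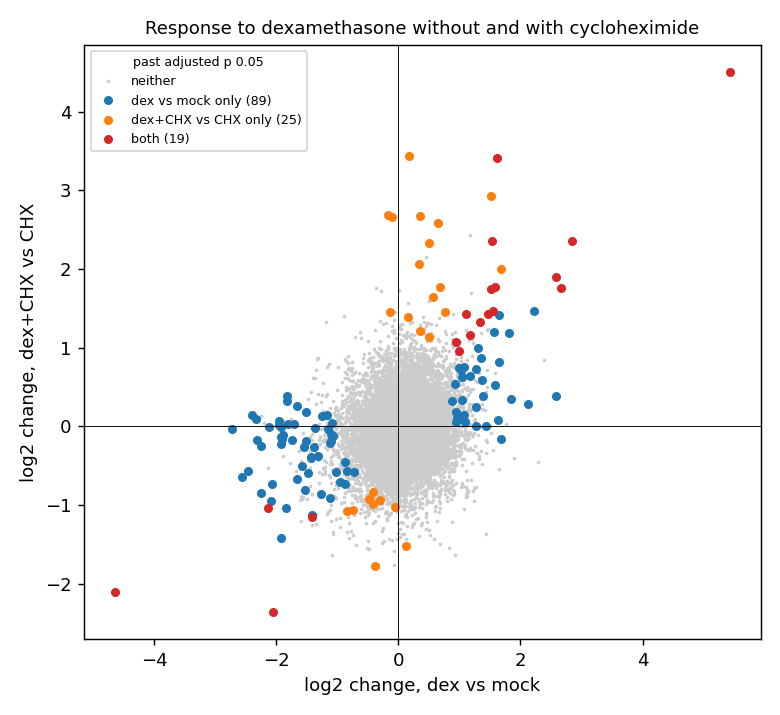
Log2 change of each tested probe set with dexamethasone against mock (horizontal axis) and with dexamethasone and cycloheximide against cycloheximide (vertical axis), with 89 probe sets past the threshold only in the former, 25 only in the latter and 19 in both. AT5G60630, at 5.43 and 4.51, lies farthest to the upper right, and AT5G55450, at -4.64 and -2.11, farthest to the left.

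In 35S::LFY seedlings, the transcription factor gene MYC3, a regulator of jasmonate responses, rose by 1.18 ± 0.16 log2 against Landsberg erecta (270.3 ± 12 against 113.6 ± 1.1, n = 2, adjusted p = 0.0137). The defensin gene PDF1.2b rose by 2.45 ± 0.30, read by a probe set whose type can share signal with related genes. CDI rose by 0.91 ± 0.16 (adjusted p = 0.0493, or 0.0558 with the lot as a block). CW14 fell by 1.99 ± 0.20, from 117.5 ± 2.5 to 22.2 ± 5.3 (adjusted p = 0.00455), and STR18 changed by -1.55 ± 0.26. Of the loci chosen after their values were seen, AT4G36700 rose by 2.56, AT1G47400 by 2.24 and AT1G09500 by 2.04, while AT3G16670 (-2.27), AT1G13650 (-1.96) and AT2G33180 (-1.84) fell. The probe set 247490_at, also chosen after, rose by 3.75 ± 0.24 (4466 ± 175.5 against 328.6 ± 85.8, adjusted p = 0.000106). It was as high in mock-treated LEAFY-GR seedlings (4060.2 and 5500), so this rise need not be a response to LEAFY. The same limit holds for PDF1.2b, with signals of 407.9 and 346.3 in mock-treated LEAFY-GR and of 156 and 238.8 in 35S::LFY.

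limma called 67 probe sets, 39 higher and 28 lower, and 25 higher and 9 lower with arrays scaled to equal medians. Of the 39 higher, 15 were also called higher in mock-treated LEAFY-GR than in Landsberg erecta and 7 lower. Of the 28 lower, 10 were also lower there and 4 higher, against 910 higher and 869 lower of all 22746. Both comparisons use the same Landsberg erecta arrays. In the 4 fits that each left out 1 array of the 35S::LFY contrast, most of its 67 calls were lost. The log2 changes ran from 1.14 to 1.23 for MYC3, 2.16 to 2.74 for PDF1.2b and 0.78 to 1.03 for CDI. They ran from -2.16 to -1.82 for CW14 and from -1.61 to -1.5 for STR18. A lone array in a group also widens the standard error, so a lost call alone does not show that a value rested on that array. Only 247490_at passed in each of these 4 fits, with log2 changes of 3.49 to 4.01. CW14 passed only without 35S::LFY replicate 1, and was lost without 35S::LFY replicate 2 (adjusted p = 0.0705), Landsberg erecta replicate 1 (0.0685) or replicate 2 (0.0657). MYC3, PDF1.2b, CDI and STR18 were lost in all 4 fits, with a highest adjusted p of 0.181, 0.146, 0.549 and 0.366.

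AT5G60630 was higher and AT5G62280 was lower in all 3 LEAFY contrasts. AT5G60630 changed by 5.43, 4.51 and 1.92 ± 0.23 log2 in turn, with a signal of 142.1 ± 21 in 35S::LFY and 30.2 ± 5.0 in Landsberg erecta. AT5G62280 changed by -2.05 ± 0.30, -2.36 ± 0.30 and -2.14 ± 0.30, and its signal was 2.3 in 35S::LFY against 44.4 ± 8.0 in Landsberg erecta. With dexamethasone and cycloheximide it read 2.2 and 3.3. Signals in these 2 groups lay below the pseudocount, so the size of the last 2 changes depends on it. Neither gene passed in the 35S::LFY contrast without 35S::LFY replicate 1, 35S::LFY replicate 2, Landsberg erecta replicate 1 or Landsberg erecta replicate 2, so the counts in all 3 were then 0 and 0. AT5G62280 was also lost with dexamethasone without dexamethasone replicate 1 (adjusted p = 0.109), dexamethasone replicate 2 (0.0654) or mock replicate 2 (0.149). With cycloheximide present it was lost without dexamethasone with cycloheximide replicate 1 (0.076), replicate 2 (0.0657) or cycloheximide replicate 2 (0.0608). Without dexamethasone with cycloheximide replicate 1 the count lower in all 3 stayed at 1 through AT5G57760, and it was 0 without dexamethasone replicate 1 or 2, dexamethasone with cycloheximide replicate 2, cycloheximide replicate 2 or mock replicate 2. The higher count was 2 without cycloheximide replicate 1 or 2. With the lot as a block AT5G57760 joined AT5G62280, which made 2 lower in all 3 (-1.41 and adjusted p = 0.0305 for AT5G57760 with dexamethasone and cycloheximide).

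A further 20 probe sets were higher in exactly 2 of the 3 contrasts, among them GH3.17, AT1G73600, AT3G52470, AT2G26390 and AT5G49770, which rose with dexamethasone with and without cycloheximide, and AT1G24140, which rose with dexamethasone and with 35S::LFY. Another 4 were lower in exactly 2, AT5G57760, AT5G55450, AT5G01210 and 266364_at. Of the 4 fits that each left out 1 array compared, AT5G55450 and AT5G01210 passed with dexamethasone and cycloheximide in 0 (highest adjusted p 0.18 and 0.13), AT2G26390 and 266364_at in 1 (0.135 and 0.167) and AT5G49770 in 2 (0.0902). With 35S::LFY, AT1G24140 and AT5G57760 passed in 0 of 4 (0.116 and 0.207). With dexamethasone alone GH3.17 passed in 0 (0.211), 266364_at in 2 (0.0524) and AT5G57760 in 3 (0.0677). Between dexamethasone without and with cycloheximide, 15 higher calls were shared (0.0668 expected of independent lists, Fisher's exact test, adjusted p = 1.61e-32) and 4 lower calls (0.0337 expected, adjusted p = 5.74e-08). By the same test dexamethasone and 35S::LFY shared 6 higher (adjusted p = 6.75e-10) and 2 lower calls (adjusted p = 0.00287). Dexamethasone with cycloheximide and 35S::LFY shared 2 higher (adjusted p = 0.00194) and 1 lower (adjusted p = 0.0159). The 35S::LFY calls behind these overlaps, and behind the opposite calls that follow, were lost when an array of that contrast was left out. Calls of opposite direction were made with dexamethasone and 35S::LFY for 2 probe sets that fell with dexamethasone, AT4G12500 and AT4G12490, as many as were lower in both, and for 1 that rose, against 0.101 and 0.0603 expected of independent lists. The contrasts share each probe set's variance estimate, so these p-values measure departure from independent lists, which alone does not show a shared response. Across all 22746 probe sets the log2 changes of these 3 pairs correlated weakly, at a Pearson r of 0.16, 0.061 and 0.078 across genes, which are not independent replicates.

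**Figure D2:**
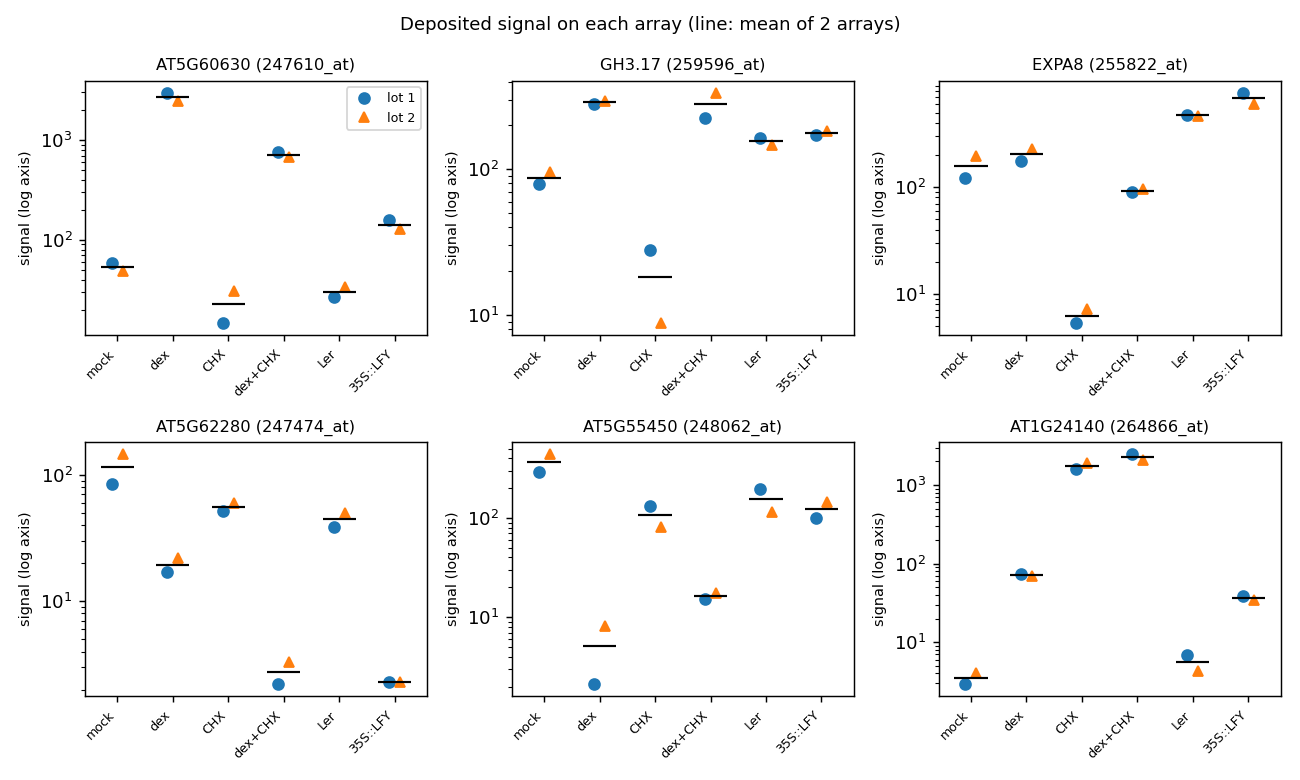
Deposited signal (log axis) on each array for 6 genes in the 6 groups, with circles for lot 1, triangles for lot 2 and a line at the mean of the 2 arrays. AT5G60630 rose from 53.6 to 2729 with dexamethasone and from 22.8 to 713.4 with cycloheximide also present, and EXPA8 stood at 6.2 with cycloheximide alone and 92.9 with dexamethasone added.

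Averaged over the 3 LEAFY contrasts, GH3.17 rose by 1.74 ± 0.17 log2 (adjusted p = 0.000666, 6 arrays against 6), EXPA8 by 1.18 ± 0.13 (adjusted p = 0.00142) and BGLU15 by 0.92 ± 0.13. HAT2 rose by 0.75, PUB23 and TBL38 by 0.71 each, AR781 by 0.66, STZ by 0.64, CCL by 0.50 and MYC3 by 0.49. XTH19 fell by 0.90 ± 0.14, as did bZIP44, a transcription factor gene (-0.89 ± 0.15), STR18 (-0.87), CW14 (-0.71), scpl35 (-0.70), SWEET11 (-0.65), PMEPCRF (-0.59) and SWEET1 (-0.51). Of these 18 genes, GH3.17 passed in 2 of the single contrasts, 14 in 1 and CCL, bZIP44 and SWEET1 in 0, so a mean here can rest largely on 1 contrast. For 5 a contrast had the opposite sign, HAT2 (-0.14), SWEET11 (0.19) and PMEPCRF (0.02) with 35S::LFY, MYC3 (-0.04) with dexamethasone and cycloheximide, and CW14 (0.14) with dexamethasone. The auxin list had a median of -0.39 and an adjusted p of 0.000777 in camera, or adjusted p = 0.053 with an estimated correlation, and 3 of its 5 members passed when adjusted over the list alone. GH3.3 had -1.12 ± 0.23 and an adjusted p of 0.0583, which was 0.0426 with the lot as a block.

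limma called 170 probe sets for this mean, 96 higher and 74 lower, of which 41 changed at least 2-fold. The count was 73 without 35S::LFY replicate 1, 88 without 35S::LFY replicate 2, 79 without Landsberg erecta replicate 1 and 88 without Landsberg erecta replicate 2. GH3.17, EXPA8, BGLU15 and scpl35 passed whichever of the 12 arrays was left out, and the other 14 genes with a symbol missed in at least 1 of the 12 fits, with a highest adjusted p between 0.056 for XTH19 and 0.14 for CCL.

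The dexamethasone response with cycloheximide differed from that without it for EXPA8, which changed by 2.31 ± 0.31 log2 more with cycloheximide (adjusted p = 0.0433, or 0.0594 with the lot as a block). Cycloheximide alone changed EXPA8 by -3.35 ± 0.22, to a signal of 6.2 ± 1.3, below the pseudocount, and with dexamethasone added it stood at 92.9 ± 5.1, still below the 159.4 ± 52.9 of mock. AT5G22580 (-2.39) and AT5G50335 (-2.72) fell with dexamethasone alone and differed by 2.53 ± 0.32 and 2.69 ± 0.37 with cycloheximide. Cycloheximide alone left them at signals of 6.5 ± 3.0 and 0.7 ± 0.2, below the pseudocount, so no further fall could be measured there. AT1G24140 rose by 2.59 with dexamethasone alone, from 3.5 ± 0.8 to 71.2 ± 2.8, and differed by -2.20 ± 0.26, but cycloheximide alone had brought it to 1733 ± 209.9, and it stood at 2276 ± 298.6 with dexamethasone added. limma called 7 probe sets here, 6 higher and 1 lower. The split was 2 higher and 0 lower with equal medians, and 1 and 1 with the hybridisation controls. With the lot as a block 2 passed, 261717_at (adjusted p = 0.00907) and AT1G24140 (adjusted p = 0.045). The count was 2 without dexamethasone replicate 1, cycloheximide replicate 1 or mock replicate 1, 1 without dexamethasone replicate 2, and 0 without dexamethasone with cycloheximide replicate 1 or 2, cycloheximide replicate 2 or mock replicate 2, against 1168 probe sets with an unadjusted p under 0.05 on all arrays.

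Cycloheximide alone changed the largest number of probe sets. DLAH rose by 7.01 ± 0.15 log2 (5835 ± 399 against 35.5 ± 2.2 in mock, n = 2, adjusted p = 8.13e-10), CCR2, a cinnamoyl-CoA reductase gene, by 6.99 ± 0.41 and the glutaredoxin gene GRX480 by 6.85 ± 0.50. NDB4 rose by 6.40, the calmodulin-like genes CML37 and CML38 by 6.30 and 5.10, B120 by 5.75, CCOAMT by 5.71, XTH18 by 5.28 and PUB23 by 5.26. The thionin gene THI2.2 fell by 4.81 ± 0.29 (10.8 ± 3.7 against 571.5 ± 79.4, adjusted p = 1.55e-07) and LCR68 changed by -4.41 ± 0.35. MCCB (-3.97) and IVD (-3.54), genes of leucine breakdown, fell, as did BCAT4, of methionine-derived glucosinolate synthesis (-3.74), DRT100 and JAL33 (-3.70 each), JAL22 (-3.55), CP5 (-3.43) and SWEET11 (-3.42).

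All 5 measured immunity genes rose with cycloheximide, WRKY53 by 3.58 ± 0.42, the pattern receptor gene EFR by 3.09 ± 0.34, WRKY22 by 2.47 ± 0.15, BIK1 by 2.37 ± 0.16 and PDF1.2 by 1.42 ± 0.45. The list's median log2 change was 2.47, with an adjusted p of 0.000777 in camera, or adjusted p = 0.053 with an estimated correlation. Of the 5 auxin response genes, GH3.3 rose from 109.4 ± 15.6 to 1243 ± 614.7 and LBD29 by 2.15 log2, WES1 fell by 1.27, and the list had an adjusted p of 0.534. Among the 6 flowering time genes AGL24 rose by 1.29 while GI, also the measured clock gene (-0.51), and SNZ (-1.08) fell, and the list had an adjusted p of 0.994. FD had 1.07 ± 0.49 and an adjusted p of 0.101, which was 0.0183 with the lot as a block. The gibberellin receptor gene GID1B rose by 2.03, and GID1A (-1.24) and GID1C (-1.30) fell. STZ rose by 4.14, the dehydrin gene COR47 fell by 3.37 and LHCB4.1 fell by 0.87. The 4 floral organ identity genes, CLV3, LAS, ARR15, RR16, COR15A, RCA, EXPA7, DFR and AT3G09630 did not pass, which left 10 higher and 7 lower of the 35 measured list loci. Without cycloheximide replicate 2, AGL24 (adjusted p = 0.0606), GI (0.0799), SNZ (0.0816) and PDF1.2 (0.199) were lost. Without mock replicate 2, GI (0.158), SNZ (0.107), LHCB4.1 (0.079) and PDF1.2 (0.0557) were lost, and without mock replicate 1, PDF1.2 (0.122).

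limma called 9727 probe sets with cycloheximide, 42.76% of those tested, and 5818 of them were lower and 3909 higher. At least a 2-fold change was seen in 6615.

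**Figure D3:**
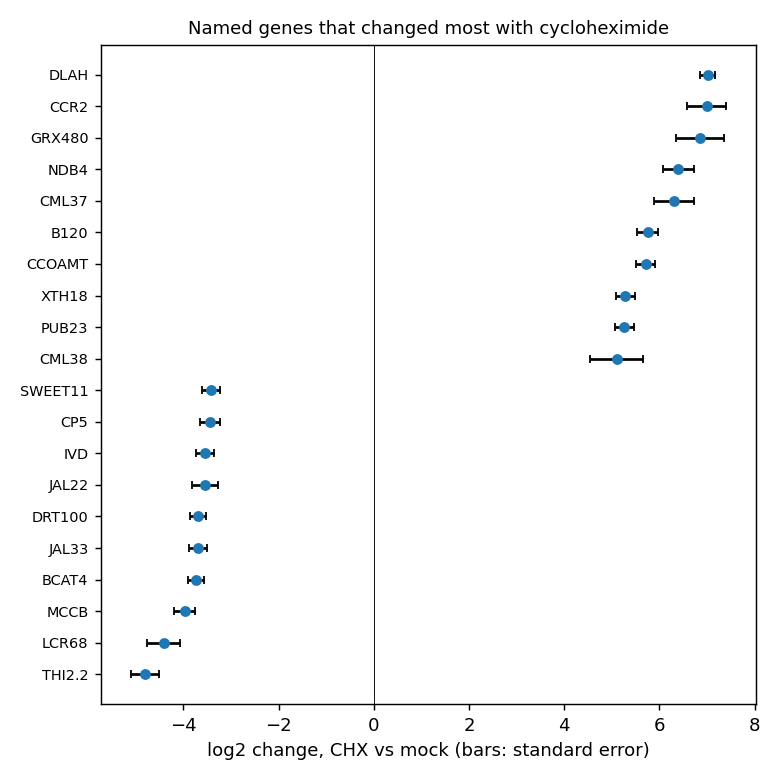
Log2 change with cycloheximide against mock (horizontal axis) of the 10 genes with a symbol that rose most and the 10 that fell most, as points with bars of 1 standard error from the fit over 2 arrays per group. The changes ran from 7.01 for DLAH to -4.81 for THI2.2.

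Mock-treated LEAFY-GR seedlings differed from untreated Landsberg erecta, a comparison in which genotype and mock treatment cannot be separated. The ratios of 3′ to 5′ signal also differed, at 1.04 ± 0.11 against 1.29 ± 0.02 for GAPDH, 1.69 ± 0.08 against 2.12 ± 0.19 for actin and 1.47 ± 0.06 against 1.85 ± 0.18 for ubiquitin, so RNA quality is not separated from them either. Of genes chosen after their values were seen, GAT1_2.1 was higher by 4.31 ± 0.38 log2 (708.4 ± 86.1 against 31.0 ± 27.4, n = 2, adjusted p = 4.39e-05), the glycosyltransferase gene UGT73C1 by 4.03 ± 0.46, PDF1.2b by 3.38 ± 0.30, STZ by 3.22 ± 0.17 and JRG21 by 3.14 ± 0.36. The cold-response gene COR15A fell by 2.30 ± 0.42, as did the glucosinolate genes AOP3 (-2.27 ± 0.20) and AOP1 (-2 ± 0.19), ATSPS4F (-2.07 ± 0.20) and BZIP34 (-2.03 ± 0.25). COR15A was lost without mock replicate 2 (adjusted p = 0.0581) or Landsberg erecta replicate 2 (0.0659), and the other 9 passed in all 4 fits that left out an array. limma called 1779 probe sets, 910 higher and 869 lower, against 1095 and 388 with equal medians and 673 and 287 with scaling to the hybridisation controls. The count was 1079 without mock replicate 1, 1143 without mock replicate 2, 844 without Landsberg erecta replicate 1 and 731 without Landsberg erecta replicate 2.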

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

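The difference between the 35S::LFY and dexamethasone responses was a test chosen after the values were seen, whereas the difference in dexamethasone response with and without cycloheximide was planned.

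For 7 probe sets the dexamethasone response differed with and without cycloheximide by a limma test of the difference itself. 3 loci that fell with dexamethasone alone were less lowered, AT5G50335 (difference 2.69 ± 0.37 log2, adjusted p = 0.0495), AT5G22580 (2.53 ± 0.32, adjusted p = 0.0433) and AT4G12500 (2.11 ± 0.27, adjusted p = 0.0433), as was the unnamed probe set 259839_at (1.84 ± 0.25, adjusted p = 0.0433). With cycloheximide alone AT5G50335, AT5G22580, 259839_at and EXPA8 had signals of 0.7, 6.5, 5.8 and 6.2, below the pseudocount. Cycloheximide alone had also brought AT4G12500 from 253 and 292.8 in mock to 39.4 and 47.6, below the 49.7 and 61.6 with dexamethasone. EXPA8 (2.31 ± 0.31, adjusted p = 0.0433) and the unnamed probe set 261717_at (2.76 ± 0.26, adjusted p = 0.00678) rose with dexamethasone in the presence of cycloheximide, by 2.67 and 2.66. AT1G24140 rose with dexamethasone alone and its difference was -2.20 ± 0.26 (adjusted p = 0.0312), with a signal of 3.5 in mock and 1733 with cycloheximide alone. 261717_at and AT1G24140 passed with the lot as a block, and the adjusted p of the other 5 was then 0.0504 for AT5G22580, 0.0523 for AT4G12500 and 259839_at, 0.0594 for EXPA8 and 0.069 for AT5G50335. None of the 7 passed under each of the 8 fits that left out an array, and 261717_at passed in 4 of them.

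The effect of 35S::LFY differed from that of dexamethasone for 23 probe sets, 15 higher and 8 lower, and the split was 15 and 3 with arrays scaled to equal medians. AT4G12500 fell with dexamethasone (-2.11) and rose with 35S::LFY by 1.75 ± 0.19, a difference of 3.85 ± 0.27 (adjusted p = 0.000361). AT4G12490 differed by 3.46 ± 0.30, AT5G55450 by 4.35 ± 0.48 and the unnamed probe set 247490_at, already high in mock-treated LEAFY-GR (4060.2 and 5500), by 3.83 ± 0.34. AT5G60630 rose in both and differed by -3.51 ± 0.33, AT1G73600 by -2.74 ± 0.32 and CW14 by -2.13 ± 0.28. The unnamed probe set 258742_at (difference -1.76) had an adjusted p of 0.0334, or 0.0506 with the lot as a block. The count was 11 without dexamethasone replicate 1, 10 without mock replicate 2, 8 without 35S::LFY replicate 1, 7 without 35S::LFY replicate 2, 11 without Landsberg erecta replicate 1 and 6 without Landsberg erecta replicate 2. AT4G12500, AT4G12490, 247490_at and AT5G60630 passed in all 8 fits that left out an array, and AT5G55450 in 7 of them (adjusted p = 0.0538 without 35S::LFY replicate 2). AT1G73600 passed in 6 and CW14 in 2 of the 8, with a highest adjusted p of 0.0681 and 0.121.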

How the results depend on the processing

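Scaling to the hybridisation controls and the difference between the 35S::LFY and dexamethasone responses were chosen after seeing the data. No called value of a named gene changed sign under any alternative run. Of 251 such values, 236 stayed called with quantile normalisation, 198 with equal medians, 241 with either other pseudocount, 177 without the trend, 152 when only the groups compared were fitted, 243 with the lot as a block and 174 with the hybridisation controls, and 227 of 227 without the dimmest probe sets. The counts below moved by over 1.5 times, and the cause was not tested unless stated. For dexamethasone (108), 61 passed without the trend, 1 with only the groups compared, 63 with the hybridisation controls, 164 at an adjusted p of 0.1 and 209 by the 2-fold rule. Fitting only the groups compared leaves fewer residual degrees of freedom, yet it raised the count for 35S::LFY. The median standard deviation between replicates was 0.141 log2 in both 35S::LFY and Landsberg erecta. It was 0.167 in mock, 0.182 with dexamethasone, 0.226 with cycloheximide and 0.18 with both. The main fit shares 1 spread per probe set, so its errors may be too wide for 35S::LFY and too narrow for cycloheximide. Whether this moved the counts was not tested. For dexamethasone with cycloheximide (44), the counts were 25 without the trend, 2 with only the groups compared, 21 with the hybridisation controls and 111 by the 2-fold rule. For 35S::LFY (67), they were 34 with equal medians, 32 without the trend, 156 with only the groups compared, 24 with the hybridisation controls and 147 by the 2-fold rule. Cycloheximide (9727) gave 5335 by the 2-fold rule. The difference in dexamethasone response (7) gave 2 with equal medians, 4 with a pseudocount of 5, 2 without the trend, 1 with only the groups compared, 2 with the lot as a block, 2 with the hybridisation controls and 328 by the 2-fold rule. The mean of the 3 contrasts (170) gave 93 without the trend, 65 with the hybridisation controls, 313 at an adjusted p of 0.1 and 33 by the 2-fold rule. Mock against Landsberg erecta (1779) gave 960 with the hybridisation controls and 864 by the 2-fold rule. The difference between the 35S::LFY and dexamethasone responses (23) gave 41 with a pseudocount of 40, 37 without the dimmest probe sets, 15 without the trend, 8 with the hybridisation controls, 42 at an adjusted p of 0.1 and 453 by the 2-fold rule. The number higher in all 3 LEAFY contrasts (1) was 2 with quantile normalisation, at an adjusted p of 0.1 and by the 2-fold rule. The number lower in all 3 (1) was 2 with a pseudocount of 5, with the lot as a block, at an adjusted p of 0.1 and by the 2-fold rule, and 0 with a pseudocount of 40 or with only the groups compared. Of the 4 gene list calls, 0 passed with an estimated correlation, and of 10 family calls 0 did. With fry 3 list calls passed. They were auxin response with 35S::LFY and for the mean (fry adjusted p = 0.0124 each) and immunity with cycloheximide (6.83e-07). Auxin response with dexamethasone did not pass with fry (0.141).

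Leaving out 1 array gave 33 to 54 calls for dexamethasone, 20 to 51 with cycloheximide also present, 1 to 2 for 35S::LFY, 7876 to 9058 for cycloheximide, 0 to 2 for the difference in dexamethasone response, 73 to 178 for the mean, 731 to 1143 for mock against Landsberg erecta, 6 to 17 for the difference between the 35S::LFY and dexamethasone responses, 0 to 2 higher and 0 to 1 lower in all 3, and 3 to 4 gene list calls. Of 1404 called values of named genes in these fits, 886 stayed called. The block ended 8 named calls and brought 4. Of these, 263216_s_at with 35S::LFY (1.00, adjusted p = 0.0395, or 0.0523 with the block) was ended and 258791_at with dexamethasone (-0.91, adjusted p = 0.0341) was brought, and the other 10 are given with their genes. The block changed no other call of a named gene and no list call but that of auxin response with dexamethasone. No gene list value could be had without the dimmest 40% of probe sets, since no list then kept 5 members. Signal over background limits dim genes such as UFO, SPL and CLV3, whose signals lay near the pseudocount and whose change could not be measured there.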

Other observations

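The families, the difference in share kept among probe sets with room to fall, the permutation of directions, the count of splits that parted the lots evenly and the share of lower calls under other scalings or where both means were bright were tests chosen after the results were seen.

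With cycloheximide some gene families shifted as a set at camera's preset correlation, but no family call passed with an estimated correlation. For comparison, limma called 5818 of all 22746 tested probe sets lower and 3909 higher with cycloheximide. Of 8 measured aldehyde dehydrogenase genes (ALDH), 6 fell, among them ALDH7B4 (-2.79 ± 0.15 log2), ALDH6B2 (-2.70 ± 0.17) and ALDH11A3 (-2.29 ± 0.23), and the family median was -1.36 (camera adjusted p = 0.0154 over 224 tests of 32 families in 7 contrasts, and adjusted p = 0.994 with an estimated correlation). Of 9 U-box ubiquitin ligase genes (PUB), 5 rose, PUB23 by 5.26, PUB24 by 4.32 ± 0.14, PUB22 by 3.61 ± 0.23, PUB19 by 2.44 ± 0.24 and PUB26 by 1.16 ± 0.25, with a family median of 1.16 (adjusted p = 0.0154, and adjusted p = 0.655 with an estimated correlation). Of 69 plastid-encoded genes 22 fell, including psbC (-1.55 ± 0.26) and rbcL (-1.44 ± 0.23), and their median was -0.53 (adjusted p = 0.0202, and adjusted p = 0.994 with an estimated correlation). These directions held under all 3 other scalings. The glycosyltransferase genes (UGT) were higher in mock-treated LEAFY-GR seedlings than in Landsberg erecta, with 9 higher and 2 lower of 47, a median of 0.22 and an adjusted p of 0.0348, and adjusted p = 0.994 with an estimated correlation. The other 6 family calls, for IQD in 2 contrasts, plastid-encoded genes in 2, EXPA and XTH, had medians of -0.34 to 0.36, and none passed with an estimated correlation.

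The probe set 247490_at, chosen after its values were seen and unnamed here, had a signal of 328.6 ± 85.8 in Landsberg erecta, 4466 ± 175.5 in 35S::LFY and 4780 ± 1018 in mock-treated LEAFY-GR (log2 3.83 ± 0.24 above Landsberg erecta, adjusted p = 6.45e-06). With dexamethasone it was 4479 ± 479.6 and with cycloheximide 5912 ± 1236, and neither differed from mock by the limma test. With both it read 4680.2 and 5529.6. It was thus high in all seedlings carrying LEAFY-GR or 35S::LFY, whatever the treatment, and low in Landsberg erecta. Whether it reads the introduced LEAFY sequence could not be checked here, so its rise with 35S::LFY need not be a response to LEAFY.

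Probe sets that fell with dexamethasone kept less of their change when cycloheximide was present than those that rose, with a median share kept of 0.171 for the 59 lower and 0.607 for the 49 higher. A permutation test of the directions gave p = 1e-04 (two-sided), but it takes probe sets read on the same arrays as independent, and a deviation of the 2 mock arrays need not act on both directions alike, so selection of extreme values stays open. The signal floor also remained a candidate explanation, because 36 of the 59 lower probe sets already lay at or below their dexamethasone mean with cycloheximide alone, and the cycloheximide mean was under 2 times the pseudocount for 18 of the 59 lower and 4 of the 49 higher. In the 5 lower probe sets whose cycloheximide mean was at least the mock mean the share was still smaller, by -0.522, which argues against a lack of room for those 5, but among the 39 with room for the full change the difference was -0.252 with a 95% bootstrap interval of -0.436 to 0.0334, which leaves the floor open for the rest. A need for newly made protein is a biological explanation that was not tested.

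More probe sets fell than rose with cycloheximide, 59.8% of the calls (56.9% to 63.0% on leaving out 1 array). The share was 57.1% with quantile normalisation, 56.2% with equal medians and 65.4% with the hybridisation controls, so it did not depend on the choice among these scalings. None of them measures the total RNA of the seedlings, so a change in that total with cycloheximide could still affect the share. The share was 64.3% among the brightest 60% of probe sets, which decides nothing about the floor, since a mean over all 12 arrays keeps a fall more easily than a rise. Compression near the floor is unlikely all the same, since 65.1% of the 6686 calls were lower where both the mock and the cycloheximide mean were at least 4 times the pseudocount (62.9% to 66.9% on leaving out 1 array). Loss of transcription of many genes and faster decay of their RNA both remain open and were not tested.

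For the mean of the 3 LEAFY contrasts, 3 of 100 drawn splits of the 12 arrays (of 108 distinct ones), the real one included, called at least as many probe sets as the real 170. Most other splits put arrays of unlike treatment or genotype into the same group, which widens the spread and lowers their counts. These splits therefore cannot decide whether a random grouping could give such a count. The highest other split called 302 and the next 212, and both parted the 8 LEAFY-GR arrays by lot and the other 4 by genotype, while the split that followed the lots throughout called 57. With the lot as a block the real split called 247. Of 31 drawn splits that parted the lots evenly in each pair of groups, 1, the real one, called as many, and the highest other called 52.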
